A study of Mus musculus with 8 samples.

How the data were processed

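RNA sequencing libraries came from microglia sorted from the spinal cords of 8 female mice, 4 wild type (WT) and 4 with the knock-in that the labels call Cd11b-P2X4mCherryIN (KI), with 1 library per mouse. Per the labels' protocols, cord tissue was dissociated mechanically, debris was removed on a Percoll gradient, and living cells that were positive for CD11b, low for CD45 and negative for Ly6C were collected. RNA was purified with an RNeasy Plus Mini kit and libraries were made with a NEBNext kit for low RNA input, per the labels' protocols. The groups and the mouse numbers that name the libraries were taken from the labels, which give no batch, age or treatment.

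Per the submitters' processing notes, STAR 2.7.5c, SAMtools 1.9, featureCounts 2.0.3, R 3.6.0, edgeR and limma were used with the mouse genome build mm10, and the notes as used here tie none of them to a step. Per the file headers, the deposited counts were made by featureCounts over exons summed by gene identifier, with paired-end input, primary alignments only, chimeric pairs left out and no strand option. The header gives no option to count a pair as 1 fragment, so both reads of a pair can add to a count; of the counts from 1 to 9, between 68.9% and 70.8% were even in each library. Without strand, reads of overlapping or antisense genes, such as Xist and Tsix, cannot be told apart. A read that maps to several places can be counted at its primary alignment, so genes with near-identical copies, such as the haemoglobin genes, Hspa1b, Ifi207 and Ifi204, the class I genes and the ribosomal protein genes, have uncertain counts. The version of the gene annotation is not given in the sources used here. The deposited count table lists 54532 genes and, for each, the summed exon length in bases, written by featureCounts per the file headers. Of the gene identifiers, 54409 were paired with a symbol through the GENCODE annotation of the same build, in which 98.33% of these had the same start and end, and the other 123 held 0.0029% of the reads. The table also holds 8 columns whose names match no label of these libraries, and these were not used here.

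Besides the counts, a table of FPKM values and a table of normalized values were deposited by the authors, with no tool given for either. From the values, the deposited FPKM is the count scaled to the library's total and to the exon length less 190 bases, and the 6648 genes of 190 bases or less are absent. The deposited normalized signal is each count divided by 1 size factor per library, and genes with 5 reads or fewer over the 8 libraries are absent. Multiplying back gave whole reads for 100% of the values, within 0.01 of a whole number. The 37 mitochondrial genes of the annotation, 13 of them protein-coding, held 0 reads in the 8 libraries, so the planned mitochondrial share was not computed.

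The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes were kept by filterByExpr (minimum count 10, minimum total 15), and KI was compared with WT by the quasi-likelihood test with robust dispersion and group as the only term. Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. Levels are given as CPM (counts relative to the library size) scaled by TMM, with the SD over the 4 libraries of a group, and log2 fold changes are KI over WT. Unless stated otherwise, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Total counts ranged from 45167483 to 54049801 reads, so 3 reads, the limit that a count of 0 allows, correspond to 0.0555 to 0.0664 CPM. Intervals are 95% intervals, and reads without molecular identifiers are not independent molecules.

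Gene lists (36, with 877 genes, 875 of them in the table) covered microglial states, immune programmes, metabolism, purinergic and calcium signalling, technical gene groups and markers of other cells the sort could hold. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1, at its preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives, and members were also adjusted over the list alone. Library measures (total reads, genes with a read, share of the 10 most abundant genes, slopes on GC content and transcript length, principal components and summed CPM of other-cell markers) were compared by 2-sided exact permutation tests. The slopes and principal components were not in the plan. Neither was the comparison of the lists' mean levels, made in the same way. With 4 libraries against 4 there are 70 assignments and the smallest p is 0.0286.

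Named genes were P2rx4, Itgam and P2rx7; up to 12 called genes per direction with a mean CPM of at least 5 and no overlap between the groups; where fewer than 6 passed, up to 6 per direction with the smallest unadjusted p and the same CPM minimum, without unnamed gene models; up to 4 members with the smallest p of each list that passed; and at most 2 members with the highest mean CPM of each other list. Camkk2, Fscn1, Lamp1, Ndufa5, Slc17a9, Srebf2 and the gene models near P2rx4 fall outside this rule and were chosen after their values were seen. Some genes that were examined are not reported here.

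Alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom with and without sample quality weights, edgeR's likelihood ratio test, 3 other filters on low counts, 2 other thresholds, limma on the log2 of the FPKM with pseudocounts of 0.1 and 1 and a minimum mean FPKM of 0.5 or none, limma on the log2 of the normalized values plus 1, a surrogate variable from sva 3.50.0 as a covariate, and leaving out each library in turn. Added after seeing the data were fits with each library's trend on GC content, or on GC content and transcript length, removed; counts halved; reads recovered from the normalized values; and both KI 513 and KI 549 left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

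The procedure was tested on data simulated from the means, dispersions and library sizes of the 17291 tested genes, 4 libraries against 4. Changes were planted only in genes with a mean CPM of at least 5, many in the same set, which eases the adjustment. Genes were drawn independently of each other, so variation shared between genes was absent. False calls in the real libraries can therefore be more frequent than in the simulated ones. The edgeR quasi-likelihood test recovered 14 of 50 genes changed 1.5-fold (28%), 33 of 50 changed 2-fold (66%), 47 of 50 changed 3-fold (94%) and 49 of 50 changed 4-fold (98%), and it called 3 unchanged genes. In 3 simulated sets with no change it called at most 0 genes, with at most 827 at an unadjusted p under 0.05, while DESeq2 called at most 11 and the likelihood ratio test at most 8.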

Results

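Microglia, the resident macrophages of the central nervous system, were profiled by RNA sequencing from the spinal cords of 4 WT and 4 KI female mice. The knock-in concerns P2X4, an ion channel opened by extracellular ATP and encoded by P2rx4, and its label also names CD11b, a surface protein of myeloid cells, and the red fluorescent protein mCherry. The series as a whole is about P2X4 in autoimmune inflammation of the nervous system, while the labels of these libraries name genotype and sex and no disease or treatment. The WT libraries held 53678232 (WT 503), 47051510 (WT 504), 49244467 (WT 506) and 50591014 (WT 527) reads on genes. The KI libraries held 45167483 (KI 513), 51755766 (KI 526), 46578694 (KI 528) and 54049801 (KI 549) reads. Each library came from its own mouse, per the labels, and no pair looked like 1 library deposited under 2 names (chi-square per degree of freedom of their counts from 28.4 to 66.2). Microglial transcripts were abundant in both groups: P2ry12, an ADP receptor, averaged 8669 ± 605 CPM in WT and 8855 ± 557 in KI (SD, n = 4 each). The lysosomal enzyme gene Lgmn averaged 8644 ± 555 and 8728 ± 608 CPM.

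The single comparison of the design asks how microglia of KI females differ from those of WT females, and the targeted gene comes first. P2rx4 (ENSMUSG00000029470, mm10 chromosome 5, 122707544 to 122729738, plus strand) was read at 793 ± 43.5 CPM in WT and 859 ± 62.7 in KI (SD, n = 4 each), and the groups overlapped. Its log2 fold change was 0.11 (SE 0.066, 95% interval −0.03 to 0.26), with an edgeR adjusted p of 0.735. P2rx7, the paralog next to it on chromosome 5 (122643911 to 122691432), averaged 291 ± 47.4 CPM in WT and 276 ± 25 in KI (log2 fold change −0.08, adjusted p = 0.937). Itgam, the gene of CD11b (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491, plus strand), averaged 311 ± 14 and 314 ± 17.9 CPM (log2 fold change 0.02, adjusted p = 0.978). Counts over whole gene models do not separate a knocked-in coding sequence from the endogenous one, so the level of P2rx4 does not check the genotype labels.

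**Figure D1:**
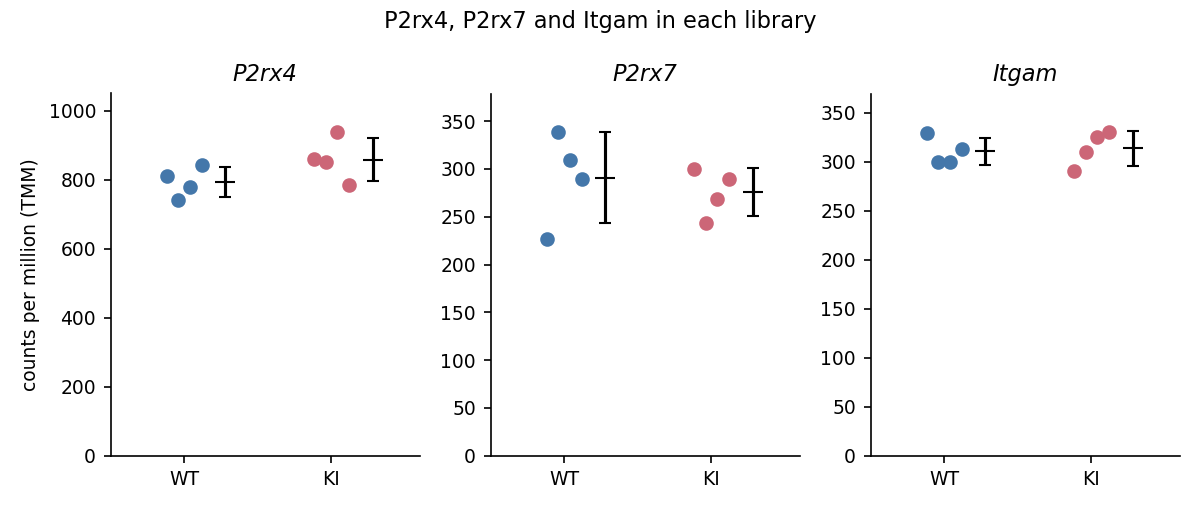
Normalised read counts (CPM, TMM scaling, vertical axes from 0) of P2rx4, P2rx7 and Itgam in the 4 WT (blue) and 4 KI (red) libraries. Each point is 1 library and the bars beside the points give the mean ± SD; the groups overlap for all 3 genes.

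Of the named genes with a mean of at least 5 CPM, the 6 per direction with the smallest p had log2 fold changes from −0.92 to 1.53. Higher in KI were the means of Acbd3, a Golgi protein (130 ± 6.66 CPM in WT, 173 ± 8.08 in KI, log2 fold change 0.41), and Ifi207, an interferon-inducible gene (6.50 ± 0.946 and 15.3 ± 2.96, 1.23). So were those of Cenpe, a kinetochore motor (2.57 ± 0.775 and 7.45 ± 2.12 CPM, 1.53, and 0.52 on log2(FPKM + 1)), and the chromatin gene Brd1 (82.0 ± 2.72 and 105 ± 5.89, 0.36). Tlk1, a kinase, had a log2 fold change of 0.47 (86.8 ± 1.87 and 120 ± 16.5 CPM), and Pias1, a SUMO ligase, of 0.24 (518 ± 15.8 and 612 ± 23 CPM). Means were lower in KI for Pias3, a related SUMO ligase (20.4 ± 1.95 and 10.8 ± 1.29 CPM, log2 fold change −0.92), Stat6, the transcription factor of interleukin 4 signalling (74.2 ± 4.07 and 52.5 ± 2.43, −0.50), and Clptm1 (202 ± 18.7 and 120 ± 20.7, −0.76). The same held for Snx20 (71.9 ± 5.58 and 45.7 ± 4.6 CPM, log2 fold change −0.66), Pip4p1, a phosphoinositide phosphatase (127 ± 18.3 and 81.3 ± 3.72, −0.64), and Paqr7, a membrane progesterone receptor (71.0 ± 3.86 and 48.9 ± 3.44, −0.54). In each of these 12 genes all 4 libraries of one group lay above all 4 of the other, but none passed the edgeR quasi-likelihood test after adjustment (adjusted p = 0.24 for Acbd3, Ifi207 and the 6 lower genes, 0.507 for the rest).

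By that test 0 of 17291 genes were called, and 1347 (7.79%) reached an unadjusted p under 0.05, 559 higher and 788 lower in KI, where 5% would be 865. DESeq2 called 248 genes (75 higher, 173 lower) and edgeR's likelihood ratio test 42 (8 higher, 34 lower), all 42 among the DESeq2 calls, while limma-voom called 0 with and without sample weights. All 12 genes above were DESeq2 calls, and 11 of them were calls of the likelihood ratio test. They were picked for the smallest p in these same counts, so these calls and the lack of overlap are no separate evidence. Among the 10171 genes with a mean of at least 5 CPM, the groups did not overlap in 615 (6.05%, where chance gives 2.86%), 313 higher and 302 lower in KI. For 92.4% of these genes the 95% interval of the fold change lay within 2-fold either way, and for 65.4% within 1.5-fold.

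**Figure D2:**
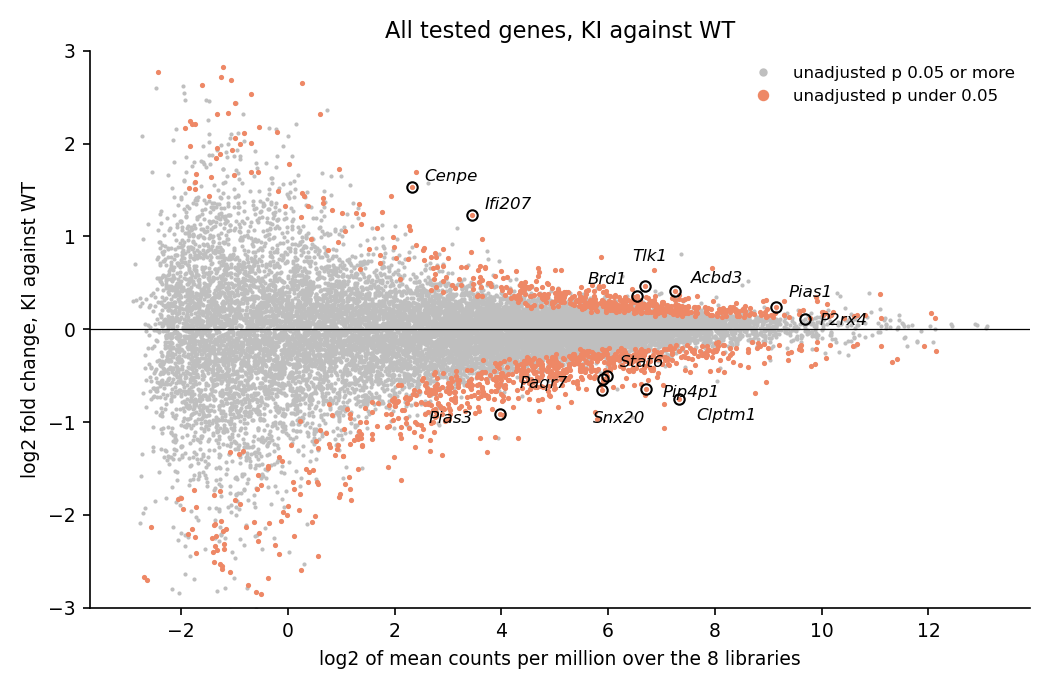
Log2 fold change of KI over WT against the log2 of mean CPM for each tested gene, with genes at an unadjusted p under 0.05 in orange and the others in grey. The circled genes are P2rx4 and the 12 named for the smallest p. In all, 17 genes lie beyond the vertical axis, and no gene passed the adjusted threshold by the edgeR quasi-likelihood test.

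Of the fixed gene lists, 11 of 31 passed camera at its preset correlation of 0.01, 8 higher and 3 lower in KI. With an estimated correlation 0 passed, and by fry 0. The estimated correlation of the 11 lists ran from 0.113 (disease-associated microglia) to 0.797 (erythroid genes), and was 0.239 for oxidative phosphorylation. Splits of the libraries 4 against 4 other than the real one passed a median of 6 lists at the preset. Here and below, rose and fell name the direction of the preset test and not an established change. Nuclear-encoded genes of oxidative phosphorylation rose slightly as a list, with 67 of 74 above 0, a median log2 fold change of 0.12 and an adjusted p of 4.8e-08 (adjusted p = 0.584 with an estimated correlation). Uqcrc1, a core subunit of complex III, averaged 457 ± 9.29 CPM in WT and 521 ± 18.3 in KI (SD, n = 4 each), and Sdhd of complex II 132 ± 8.23 and 154 ± 9.18. Atp5k of the ATP synthase averaged 14.6 ± 1.18 and 18.9 ± 2.31 CPM, and Ndufv2 of complex I 120 ± 11.4 and 139 ± 6.07. Genes of disease-associated microglia, a state described around damaged tissue, also rose as a list (23 of 29 above 0, median 0.18, adjusted p = 0.000211, and adjusted p = 0.566 with an estimated correlation). The growth factor gene Igf1 averaged 2.49 ± 1.95 CPM in WT and 8.08 ± 1.98 in KI. WT 504 held 5.37 CPM of it against 1.25 to 2.01 in the other WT libraries, and the log2 fold change of 1.70 was 2.40 without WT 504 and 0.55 on log2(FPKM + 1). Cybb, an NADPH oxidase subunit, averaged 25.1 ± 6.80 and 39.2 ± 7.94. Ccl6 averaged 525 ± 15.4 and 593 ± 40.4 CPM, and Aplp2 had the opposite sign (204 ± 8.80 and 175 ± 17). Chemokine genes rose with 15 of 16 above 0 and a median of 0.25 (adjusted p = 0.00127, and adjusted p = 0.566 with an estimated correlation). Among them Cxcl16 averaged 118 ± 8.27 and 144 ± 16.4 CPM, Ccl9 221 ± 12.4 and 235 ± 5.18, and Cxcl10 2.89 ± 1.41 and 4.59 ± 1.66. The mean level of the chemokine list (log2, centred over the 8 libraries) was lowest in WT 504 of the WT libraries (−0.583) and KI 526 of the KI libraries (−0.217), as was that of the immediate early and stress list (−1.04 and −0.666). It was highest in KI 528 (0.655) and KI 549 (0.403), where the other list stood at 0.364 and 0.29, while in WT 506 (−0.231 and 0.405) and KI 513 (−0.152 and 0.626) the lists had opposite signs. Summed monocyte markers were at 253 ± 14.2 CPM in WT and 291 ± 15.2 in KI without overlap, but most of the sum was Ms4a6b, whose own groups overlapped. The mean level of the monocyte list did not pass an exact permutation test (p = 0.629). Erythroid genes fell, 7 of 7 below 0 with a median of −0.96 (adjusted p = 4.25e-05, and adjusted p = 0.566 with an estimated correlation). The globin genes Hbb-bs (178 ± 76.1 CPM in WT, 85.5 ± 45.5 in KI) and Hba-a2 (73.5 ± 31.1 and 37.8 ± 19) varied widely within both groups, and Alas2 of haem synthesis averaged 6.77 ± 2.27 and 4.27 ± 0.824. Over all genes, and also adjusted over the list alone, the edgeR quasi-likelihood test called 0 members of these lists. At an unadjusted p under 0.05 were 9 members of the oxidative phosphorylation list (all higher), 9 higher and 2 lower of the disease-associated list, 2 of the chemokines and 3 of the erythroid list. Ccl6 is in both the disease-associated and the chemokine list and is counted in each, so these lists are not separate evidence. DESeq2 called Uqcrc1 (adjusted p = 0.00631), Ndufa5 (0.0464) and Igf1 (0.0305). At the preset correlation, each of these lists still passed camera when each of the 8 libraries was left out in turn. Their mean levels per library (log2, centred over the 8 libraries) did not pass an exact permutation test, even before adjustment. Its p was 0.0571 for oxidative phosphorylation, 0.0857 for the disease-associated list, 0.229 for chemokines and 0.143 for erythroid genes. For oxidative phosphorylation, WT 503 (0.0236) lay above KI 513 (−0.0115).

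The other lists that passed lost their camera call when 1 library was left out. Homeostatic microglial genes fell as a list (19 of 30 below 0, median −0.08, adjusted p = 0.0269, and adjusted p = 0.693 with an estimated correlation). Csf1r, the receptor on which microglia depend for survival, averaged 2866 ± 242 CPM in WT and 2250 ± 232 in KI (SD, n = 4 each), with no overlap of the groups and a DESeq2 adjusted p of 0.0493. Cx3cr1, the fractalkine receptor, averaged 4859 ± 380 and 4135 ± 322 CPM. Levels of the transporter genes were 734 ± 73.7 and 584 ± 82.5 for Slco2b1 and 840 ± 63.1 and 719 ± 54.7 for Slc2a5. The call was lost without WT 504 (0.226), WT 527 (0.0669) or KI 526 (0.171). Type I interferon genes rose with 26 of 38 above 0 and a median of 0.11 (adjusted p = 0.00498, and adjusted p = 0.693 with an estimated correlation), but not without WT 506 (0.199). Besides Ifi207, the means were 118 ± 5.67 and 135 ± 11.5 CPM for Slfn8, 31.7 ± 6.52 and 41.1 ± 6.55 for Ifi204, and 82.1 ± 10.9 and 97.1 ± 9.13 for Rtp4. Cell cycle genes rose with 31 of 40 above 0 and a median of 0.23 (adjusted p = 0.00277, and adjusted p = 0.693 with an estimated correlation), but not without WT 504 (0.105) or KI 513 (0.221). Beyond Cenpe, the replication factor Mcm4 averaged 20.5 ± 8 and 31.4 ± 5.25 CPM, Spc25 5.06 ± 2.71 and 8.70 ± 1.26, and the proliferation marker Mki67 6.72 ± 3.29 and 10.2 ± 2.66. Genes of class II antigen presentation rose with 13 of 15 above 0 and a median of 0.06 (adjusted p = 0.0415, and adjusted p = 0.693 with an estimated correlation). Cd86, a costimulatory molecule, averaged 1089 ± 70.5 and 1215 ± 33.7 CPM, while H2-Ab1 (42.7 ± 15.0 and 73.2 ± 34.2), Cd74 (191 ± 63.6 and 302 ± 120) and H2-Oa (35.6 ± 3.42 and 39.3 ± 1.95) had overlapping groups. This call was lost without WT 504 (0.0629), WT 506 (0.126), WT 527 (0.189), KI 526 (0.0816) or KI 528 (0.494). The mean level of the class II list (log2, centred over the 8 libraries) was highest in KI 528 (0.707), as were those of monocyte (0.939) and border-associated macrophage genes (1.43). In KI 513 (−0.424 and 0.261) and KI 526 (0.245 and −0.493) the class II and monocyte lists had opposite signs.

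Immediate early and stress genes, which tissue dissociation is known to induce, rose with 26 of 34 above 0 and a median of 0.31 (adjusted p = 0.00498, and adjusted p = 0.693 with an estimated correlation). Klf6 averaged 1129 ± 250 CPM in WT and 1452 ± 405 in KI, and the heat shock gene Hsp90aa1 107 ± 16.6 and 139 ± 45.6. Hspa1b averaged 3 ± 1.16 and 6.11 ± 4.77 CPM, and Nr4a3 0.178 ± 0.0831 and 0.560 ± 0.378. The list's mean level ranged from −1.04 in WT 504 to 0.626 in KI 513 (log2, centred over the 8 libraries), and the call was lost without WT 504 (0.824), KI 513 (0.263) or KI 528 (0.0611). Cytosolic ribosomal protein genes rose with 59 of 77 above 0 and a median of 0.07 (adjusted p = 0.0112, and adjusted p = 0.693 with an estimated correlation). Rps3 averaged 340 ± 16.3 and 373 ± 23 CPM, Rpl21 32.1 ± 1.45 and 36.4 ± 1.47, and Rps25 51.8 ± 2.27 and 57.2 ± 3.82. That call was lost without WT 506 (0.117), WT 527 (0.0737), KI 528 (0.0599) or KI 549 (0.0751), and with the GC and length trends removed (0.39). Genes of glycolysis and the hypoxia response fell with 19 of 25 below 0 and a median of −0.09 (adjusted p = 0.047, and adjusted p = 0.693 with an estimated correlation). Pkm, which makes pyruvate, averaged 244 ± 27.7 and 201 ± 7.21 CPM without overlap, Ldha 163 ± 9.12 and 145 ± 6.73, Hk3 61.4 ± 8.44 and 51.3 ± 7.05, and Pfkp 2.58 ± 1.09 and 1.13 ± 0.851. It was lost without WT 506 (0.0548), WT 527 (0.341), KI 513 (0.0571), KI 526 (0.413) or KI 549 (0.0626), and with the GC trend removed (0.302). With GC and length trends removed, the homeostatic (0.0726) and class II (0.0867) lists did not pass either. In all the lists that depended on 1 library, the edgeR quasi-likelihood test called 0 members over all genes. Adjusted over the list alone, it called 1 each of the cell cycle (Cenpe, 0.024) and interferon lists (Ifi207, 0.00353). The likelihood ratio test called both over all genes (adjusted p = 0.0105 for Cenpe and 0.000173 for Ifi207). At an unadjusted p under 0.05 were 6 lower and 1 higher of the homeostatic list, 2 interferon, 3 cell cycle, 3 class II and 1 immediate early gene, all higher, 0 ribosomal protein genes and 2 lower genes of glycolysis. The slope of the libraries on GC content averaged 0.0554 ± 0.0470 in WT and −0.0554 ± 0.0709 in KI (log2 per 10 points, SD, n = 4 each), which did not pass (exact permutation p = 0.0571, adjusted 0.419). Their slope on transcript length did not pass either (exact permutation p = 0.0571, adjusted 0.419).

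**Figure D3:**
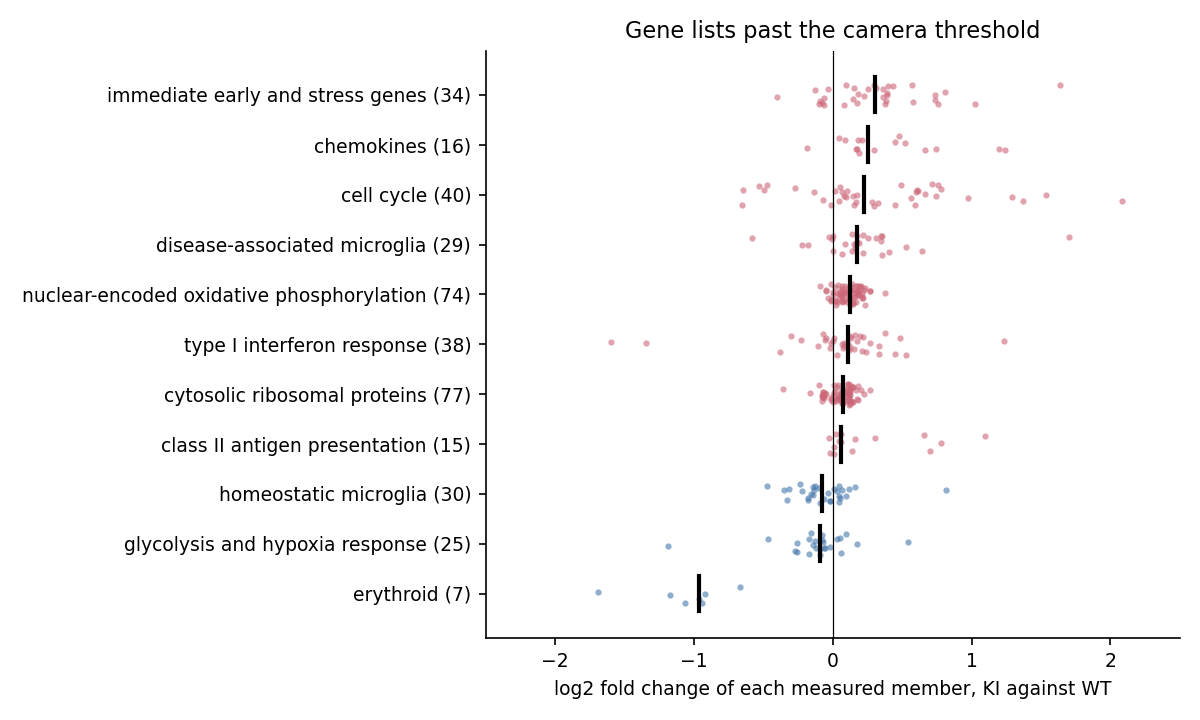
Log2 fold change of KI over WT for each measured member of the 11 lists that passed camera, with the number of members in brackets. Points are genes and black bars are list medians, from 0.31 for immediate early and stress genes to −0.96 for erythroid genes.

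Several microglial programmes did not pass camera. Purinergic receptors and ectonucleotidases, the family of P2X4 itself, had a median of −0.10 (adjusted p = 0.318), with P2ry12 at a log2 fold change of 0.03 and P2ry13 at −0.13 (3691 ± 387 and 3373 ± 180 CPM). Calcium channels and calcium-dependent signalling had a median of −0.07, a mean of 0.01 and a downward test (adjusted p = 0.68), with Calm2 at 0.11 and Camk1 at −0.20. With 1 library left out, Camk1 ranged from −0.25 to −0.09. Inflammasome genes had a median of 0.05 (adjusted p = 0.259; Nek7 −0.09, Casp8 0.03), and inflammatory cytokines and NF-kB targets of 0.09 (adjusted p = 0.491; Cd83 0.18, Tlr2 −0.01). The median was 0.03 for class I antigen presentation (adjusted p = 0.874; B2m 0.10, H2-D1 −0.06), −0.05 for alternative activation (adjusted p = 0.64; Il13ra1 0.06, Stab1 −0.15) and −0.00 for complement (adjusted p = 0.734; C1qb −0.02, C1qc −0.14). Trophic and repair factors had a median of −0.01, a mean of 0.15 and an upward test (adjusted p = 0.745), with Pros1 at 0.05 and Grn at −0.21. Lysosomal and phagocytic genes had a median of −0.01 (adjusted p = 0.178, and 0.0414 without WT 506). By the quasi-likelihood test adjusted over the list alone, 2 of their 50 measured members were called, among them the lysosomal membrane protein gene Lamp1 (534 ± 61.8 CPM in WT and 332 ± 60.2 in KI), and 0 over all genes. Cholesterol synthesis genes had a median of −0.06 (adjusted p = 0.318; Msmo1 −0.04, Ebp 0.19). Genes of lipid efflux and storage had a median of −0.05, a mean of 0.01 and a downward test (adjusted p = 0.985), with Apoe at 0.35 (837 ± 75.6 and 1068 ± 249 CPM) and Abcg1 at 0.32. KI 528 held 1419 CPM of Apoe, and without it the log2 fold change was 0.18. The unfolded protein response had a median of −0.01 (adjusted p = 0.874; Hspa5 0.04, Pdia3 0.00). In all of these lists the edgeR quasi-likelihood test called 0 genes over all genes tested. Members called by the likelihood ratio test included Lamp1, and those called by DESeq2 included Lamp1, Srebf2, Slc17a9 and Camkk2.

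No list of markers of other cell types passed camera besides the erythroid genes. Monocyte genes had a median of 0.43 with 9 of 10 above 0 (camera adjusted p = 0.055; Ms4a6b 0.11, Ms4a4c 0.54, and 0.33 without WT 506), and passed without WT 503 (0.0133), KI 526 (0.00975) or KI 549 (0.0214) and with a CPM of at least 1 in 4 libraries as filter (0.0167). Their summed level was 253 ± 14.2 CPM in WT and 291 ± 15.2 in KI (SD, n = 4 each), with an exact permutation p of 0.0286, the smallest possible, adjusted 0.419. Ms4a6b made up most of that sum (200 ± 10.1 and 215 ± 17 CPM), and its groups overlapped. The monocyte list's mean level (log2, centred over the 8 libraries) was lowest in KI 526 (−0.493) and highest in KI 528 (0.939), with an exact permutation p of 0.629. Dendritic cell genes had a median of −0.16 (adjusted p = 0.055; Siglech 0.01, Tcf4 −0.05) and passed without WT 506 (0.032), KI 513 (0.0462) or KI 528 (0.0478) and with the GC trend removed (0.0357). Adjusted over the list alone, 1 of its members was called, the actin-bundling gene Fscn1 (84.7 ± 7.45 and 64.2 ± 5.07 CPM). Border-associated macrophage genes had a median of 0.35 (camera adjusted p = 0.819). Stab1 was at −0.15 and Mrc1 at 0.41, the latter from 0.24 without KI 549 to 0.65 without WT 506. The summed level of this list was 164 ± 8.78 CPM in WT and 154 ± 12.6 in KI (exact permutation p = 0.314). B cell genes had a median of −0.02, a mean of −0.48 and an upward test (0.874; Ighm −0.02, Cd79b 0.11). The median was 0.03 for astrocyte genes (0.672; Slc1a3 0.04, Aldoc −0.08) and −0.21 for oligodendrocyte genes (0.259, and 0.0224 without KI 526; Trf 0.02). Neuronal genes had a median of 0.19 with an upward camera and a downward fry test (0.874; Meg3 0.26, Snhg11 −0.16), and endothelial and mural genes of −0.02 (0.874; Slc2a1 −0.25, and −0.12 without KI 526; Pecam1 0.02). Too few members were measured to test neutrophils (4), T and NK cells (3; Il7r 0.08, Lck −0.88, from −1.88 without KI 513 to −0.11 without WT 504), sex-linked genes (2; Xist 0.05, Tsix 0.09) and ependymal cells (1; Tmem107 0.25, and −0.05 without KI 528). Of the neutrophil genes, Csf3r averaged 303 ± 34.7 and 241 ± 16.1 CPM and was called adjusted over the list alone (0.0171). Csf3r made up most of the summed neutrophil level (311 ± 34.5 CPM in WT and 264 ± 33.6 in KI). Ngp averaged 3.08 ± 5.90 and 9.20 ± 12.9 CPM, with 0 in WT 527 and KI 549. Its log2 fold change of 1.58 was 6.07 without WT 504 and 0.03 without KI 528. The counts do not tell whether Csf3r or Fscn1 was read from microglia or from other cells. Erythroid genes summed to 403 ± 172 CPM in WT and 201 ± 105 in KI (SD, n = 4 each; exact permutation p = 0.114, adjusted 0.502). No library measure passed after adjustment, but 1 measure alone could not have passed, even at the smallest p of 0.0286. The adjusted values therefore do not show that the libraries were alike. Principal component 1 (17.4% of variance) set KI 549 apart and component 2 (17%) KI 513.

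Next to P2rx4, Camkk2 had the lowest p of the 20 nearest tested genes, a choice made after its values were seen. This gene of a calcium-dependent kinase (ENSMUSG00000029471, mm10 chromosome 5, 122731170 to 122779409, minus strand) lies 1432 bases beyond P2rx4. It averaged 28.1 ± 2.41 CPM in WT and 18.0 ± 2.94 in KI (SD, n = 4 each) without overlap, a log2 fold change of −0.64 (SE 0.148), with an adjusted p of 0.507 by edgeR and 0.00431 by DESeq2. P2rx4, at a mean of 793 CPM in WT and 859 in KI, ends facing Camkk2 on the opposite strand. The counts carry no strand, so a read from P2rx4 that ran on into an exon of Camkk2 would be counted for Camkk2. Among its neighbours, Anapc5 had a log2 fold change of −0.06, Ift81 of 0.11, Rnf34 of 0.18, Kdm2b of −0.32 and Orai1, a calcium channel subunit, of −0.08. The unnamed gene models Gm43360 (1.31 ± 0.524 and 0.114 ± 0.138 CPM) and Gm43411 (3.31 ± 1.49 and 1.1 ± 0.453) also had an unadjusted p under 0.05 and were DESeq2 calls (adjusted p = 0.0168 and 0.0359); they lie within Atp2a2 and Kdm2b on the same strand, so their counts are uncertain.

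**Figure D4:**
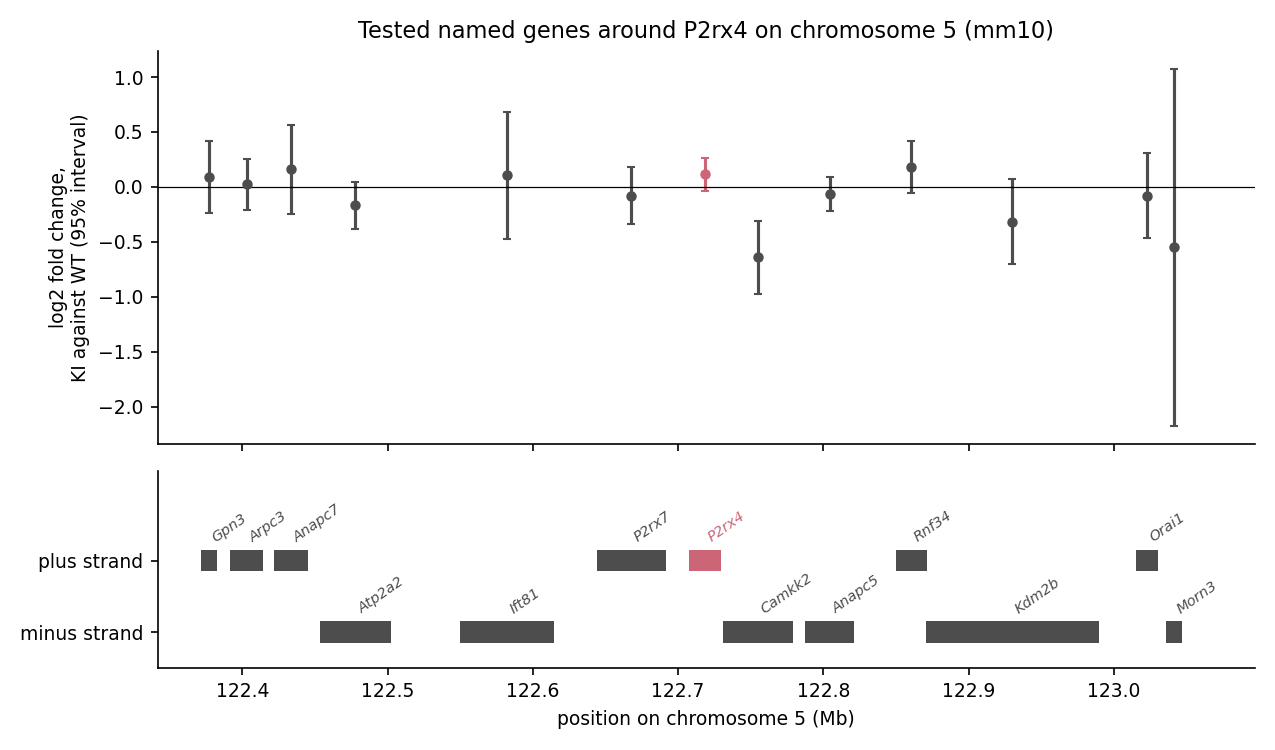
Log2 fold change of KI over WT with its 95% interval (upper panel) for tested named genes around P2rx4, by position on mm10 chromosome 5 in megabases, and the extent and strand of each gene (lower panel). The interval of Camkk2 lies below 0 and that of P2rx4 (red) spans 0.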

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

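The comparisons of the neighbours of P2rx4 with other genes, the count of reads on scaffold genes, the fits with a GC trend removed and the random lists matched on length were chosen only after the results they concern were seen. The fits without each library in turn and the estimated correlation were planned before. In each group of 4 libraries, the library farthest from the rest was found by its gap to the nearest other library, divided by the range of the group. Of 262 groups examined, 17 had a ratio above the 95% critical value, where 5% would be 13.1, so chance alone gives about as many.

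Among WT libraries, WT 504 stood apart for Tlk1 (0.838; 89.6 against at most 86.2 CPM) and Ngp (0.977; 11.9 against at most 0.275). WT 506 stood apart for Pias3 (0.969; 17.5 against at least 21.4 CPM), Stab1 (0.83; 141 against at least 152) and Il7r (0.833; 111 against at most 103). WT 503 stood apart for Stat6 (0.875; 68.2 against at least 75.9 CPM) and H2-Ab1 (0.833; 65.0 against at most 37.5). Among KI libraries, KI 549 stood apart for Grn (0.85; 1034 against at most 847 CPM), Camk1 (0.846; 466 against at least 640) and Camkk2 (0.908; 13.6 against at least 19.2). KI 513 stood apart for Ebp (0.923; 176 against at least 192 CPM) and Slc17a9 (0.889; 11.6 against at most 8.65), and KI 528 for Tsix (0.842; 6.64 against at most 5.79). KI 526 stood apart for Meg3 (0.841; 76.3 against at most 31.0 CPM), the summed level of neuronal genes (0.882; 114 against at most 43.2) and the number of genes with a read (0.884; 27800 against at most 26584). In the 8 libraries, all from females, the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y held 34, 15, 37 and 26 reads in all, above the 3 reads that a count of 0 allows; per library they came to 6 to 27 reads, or 0.122 to 0.5 CPM, beside 186282 reads of Xist.

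The oxidative phosphorylation list was higher in KI by a median log2 fold change of 0.12. A GC bias between libraries was argued against by the fit with each library's GC trend removed, in which the camera adjusted p was 7.72e-12 and the median 0.15. A single deciding library was argued against by the highest camera adjusted p without any 1 library, 0.000107 (without WT 506). Both p-values used the preset correlation. The median lay at percentile 99.9 of 10000 random lists matched on transcript length and expression. Those lists had a median of 0.08 themselves, so genes of such length and expression lay above 0 in general. Their genes were drawn independently and lack the list's shared variation, so the percentile does not decide whether transcript length was the whole cause. With GC and length trends removed, the list still passed camera at the preset correlation. Shared variation between the genes of the list stays open, since with an estimated correlation the adjusted p was 0.584. An effect of the genotype on these genes is a candidate explanation that was not tested apart from these.

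Camkk2 was lower in KI by a log2 fold change of −0.64 (SE 0.148). A GC bias as the cause was argued against by the fit with the GC trend removed, which gave −0.58 (SE 0.155, adjusted p = 0.657). A local change around the altered P2rx4 gene could lower several neighbours, and 3 of the 20 nearest tested genes, Camkk2 included, had an unadjusted p under 0.05, against 1344 of 17271 others (1-sided Fisher's exact p = 0.201). DESeq2 called the same 3, against 226 of the others (1-sided Fisher's exact p = 0.00221, and 0.0255 without Camkk2 itself), but this was looked at after both sets of values were seen and 2 of the 3 are gene models with uncertain counts, so a local change stays open. Without KI 549, the lowest library, the log2 fold change was −0.53, and an effect of the P2X4 change on Camkk2 through the cell stays open and was not tested. Whether reads from P2rx4 entered the Camkk2 count was not tested either.

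The 37 mitochondrial genes held 0 reads in every library, although their transcripts are abundant in living cells. A candidate explanation is that sequence names of the annotation and of the alignment do not match. Reads on genes of the unplaced scaffolds would then be missing too, and their 86 genes held 0 reads in the 8 libraries together, which is consistent with that explanation but does not establish it. No biological explanation was tested.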

How the results depend on the processing

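The fits with GC or length trends removed, with halved or recovered counts and without both KI 513 and KI 549 were chosen after seeing the data. The edgeR quasi-likelihood count of 0 called genes held with every other scaling, filter and threshold, with a surrogate variable, with both forms of limma-voom, with the normalized values and with each of the 8 libraries left out (0 to 0). DESeq2 called 248 genes (75 higher, 173 lower), the likelihood ratio test 42 (8 higher, 34 lower), and limma on log2(FPKM + 1) 1, which was lower (Gm49203, adjusted p = 0.0306); with a pseudocount of 0.1 it called 0 with and without the filter. The cause was not tested. At an unadjusted p under 0.05 there were 1347 genes, from 1019 (without WT 506) to 1643 (without KI 549) with 1 library left out, 2353 by DESeq2 and 2597 without a filter, where more genes were tested. The log2 fold change of P2rx4 ranged from 0.07 to 0.16 with 1 library left out and from 0.10 to 0.17 otherwise, and was called in no fit. Of the passing lists, 8 higher and 3 lower, 0 and 0 were left with an estimated correlation and 0 and 0 by fry, which replace the preset correlation or the comparison with other genes. With 1 library left out, 5 to 9 lists were higher (5 without WT 504, WT 506 or KI 528) and 1 to 4 lower (1 without WT 527). Lists lower fell to 1 with GC and length trends removed, and lists higher to 5 without KI 513 and KI 549; the cause was not tested. Among values of named genes, 857 of those with 1 library left out moved by less than the standard error and 15 by more, and with other settings 2276 by less and 66 by more, while 35 became calls, all by DESeq2 or the likelihood ratio test. No list that passed and no gene called in any fit changed sign, but the log2 fold change of 28 of the 109 genes followed did, 20 of them with 1 library left out, none of them called. Among these, P2rx7 ranged from −0.18 to 0.00 with 1 library left out (above 0 without WT 504), Meg3 from −0.27 to 0.53 (below 0 without KI 526), Snhg11 from −1.22 to 0.23 and Aldoc from −0.49 to 0.29, and Ngp from −0.52 to 2.39 with other settings and from 0.03 (without KI 528) to 6.07 (without WT 504) with 1 library left out. On log2(FPKM + 1) the log2 fold change of Cenpe was 0.52 and that of Igf1 0.55, against 1.53 and 1.70 from counts. Both have a low FPKM (means of 5.01 and 5.29 CPM over 8620 and 9904 exon bases), so the added 1 by itself shrinks their fold changes. Lck, at −0.88, reached −4.21 without KI 513 and KI 549. No paired analysis was possible because the groups share no mouse number. With 4 libraries in each group, genes changed 1.5-fold were mostly missed in simulated data (28% recovered), so smaller changes are not excluded.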

Other observations

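The splits of the libraries counted below for edgeR calls, unadjusted p-values and passing lists were run only after the real counts were seen; those for DESeq2 and the likelihood ratio test were set before their other splits were seen. Tested for change in either direction by fry, 7 lists passed: dendritic cells (adjusted p = 0.000113), lysosome and phagocytosis (0.000113), calcium signalling (0.000312), lipid efflux and storage (0.013), cholesterol synthesis (0.0483), oxidative phosphorylation (0.0483) and disease-associated microglia (0.0483). These tests do not compare a list with other genes. In the cholesterol list, Srebf2, the transcription factor that drives the pathway, averaged 19.8 ± 2.02 CPM in WT and 13.9 ± 0.854 in KI (SD, n = 4 each; log2 fold change −0.51, adjusted p = 0.507 by edgeR and 0.00115 by DESeq2). In the purinergic list, Slc17a9, the vesicular transporter that loads ATP into vesicles, averaged 14 ± 1.36 and 9.2 ± 1.6 CPM (log2 fold change −0.60, adjusted p = 0.517 by edgeR and 0.0161 by DESeq2). Both genes were chosen after their values were seen. Of the 248 DESeq2 calls, 12 were in a fixed list, 229 were tested by edgeR, and 227 of those had an unadjusted p under 0.05 there.

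The 8 libraries can be split 4 against 4 in 35 ways. For the 0 genes called by edgeR's quasi-likelihood test the count of splits decides nothing, since all 35 reach 0 by construction; the highest other called 2. The real split had 1347 genes at an unadjusted p under 0.05, a count that 2 of the 35 reached (highest other 1426), and 11 lists that passed camera, which 5 of the 35 reached (highest other 16). DESeq2 called 248 genes in the real split, and 3 of the 35 reached that (highest other 394); the likelihood ratio test called 42, and 3 of the 35 reached that (highest other 113). Chance cannot be excluded for the counts at an unadjusted p under 0.05, of passing lists, of DESeq2 and of the likelihood ratio test. The split with 1426, 394 and 113 exchanges WT 503 and KI 549, and the other that reached the DESeq2 and likelihood ratio counts (260 and 58, with 1210 at an unadjusted p under 0.05) exchanges WT 504 and KI 549. Both were singled out after the counts were seen. Whether any of these libraries has a wrong genotype label was not tested, and the level of P2rx4 does not check it. The median of the other splits was 650 genes at an unadjusted p under 0.05, 6 passing lists, 69.5 DESeq2 calls and 9.5 likelihood ratio calls.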
